A study of Mus musculus with 12 samples.

How the data were processed

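Trigeminal ganglion neurons, the sensory neurons of the face and mouth, were taken from mice into primary culture on laminin and received a miRNA by transfection. The labels put the 12 arrays into 4 groups of 3: scramble miRNAs, miR-21, miR-34a and miR-324. Total RNA was isolated with a column kit for small samples and hybridised as biotin-labelled cDNA to Clariom S Mouse arrays, which measure most genes with 1 probe set, called a probe here. The labels do not say which arm of miR-324 was used. They also do not say that the arrays of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

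The deposited values are log2 signals made with Transcriptome Analysis Console 4.0 and the robust multi-array average (RMA), per the submitters' processing notes. RMA corrects the background, normalizes arrays to a common distribution and summarises the probes of a gene. It removes any change in total signal between arrays, and values close to the floor of the array understate differences. The median signal of the 12 arrays lay between 5.91 and 6.06, the lowest value was 1.71 and the highest 19.77. Array data have no read depth, so precision is limited by the number of arrays. No array held the same values as another.

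The table has 22206 probes. A platform table paired 19572 of them with 1 gene symbol and none with several, and 2634 were unnamed here. All 19572 gene identifiers matched the RefSeq table of GRCm38.p6, and 0 symbols differed from it. The 19572 named probes stand for 19505 symbols, of which 55 have more than 1 probe. For gene lists the probe with the highest mean signal was taken for each symbol. No genome sequence or 3′ untranslated regions were used here, so the test of seed sites fixed for each miRNA was not run.

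Group means were fitted to the log2 values of all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes), which left 8 residual degrees of freedom. Each miRNA was compared with scramble, and the miRNAs were compared with each other. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 19572 named probes. Every adjusted p of a single gene is from this limma fit unless another setting is named, and all tests were two-sided. Differences are log2 values, given with the standard error (SE) of the fit. Group levels are the mean ± standard deviation (SD) of 3 arrays.

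Gene lists were written for cell types of a ganglion culture, for neuronal identity and for stress, growth and metabolic programmes. They comprised adrenergic and sympathetic genes, cholinergic genes, sensory neuron genes, pan-neuronal genes, axon growth and guidance genes, nerve injury and regeneration genes, and neural progenitor and pluripotency genes. Cell type lists covered satellite glia, myelinating Schwann cells, fibroblasts, endothelial cells, mural cells, macrophages, T and mast cells, and erythroid cells. Further lists held cell cycle, interferon response, inflammatory and NF-kB, p53 target, integrated stress response, immediate early, oxidative phosphorylation and cholesterol synthesis genes. The remaining lists held reported targets of each of the miRNAs. Of 26 lists 25 were tested, because only 2 erythroid genes were measured and 3 were needed. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 25 lists and 3 comparisons against scramble (75 tests), and separately over the comparisons between miRNAs. The camera test with an estimated correlation, and fry, were alternatives. Of the 75 tests against scramble camera called 32, and 0 of these calls held with an estimated correlation or with fry.

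Genes named in the text follow a fixed rule. Among probes with 1 symbol that is not a predicted or numbered placeholder, and with the 3 arrays of the miRNA group all above or all below the 3 scramble arrays, the 8 largest rises and 8 largest falls past the threshold were taken. Where fewer passed, the remaining places went to the smallest unadjusted p in that direction. Up to 4 members of each list past the threshold were added, and Th, Dbh, Pdcd4, Cdk6 and Sirt1 were named in every comparison with scramble. A further gene of that rule was not analysed here. Between miRNAs the 4 largest differences of each direction were taken. Levels of Tubb3, Snap25, Mki67, Csf1r, Cdh5, Eif2s3y, the pituitary hormones and other single examples from lists were added after their values were seen.

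The groups, tests, lists, naming rule and alternatives were chosen before the data were examined, apart from those named as later additions. The alternatives were quantile normalization of the values again, centring each array on its median, only probes brighter than the median probe, a variance prior with a trend, array weights, only the groups compared, no moderation of variances, an unadjusted p under 0.05 with at least a 2-fold difference, the number in the label as a block, the label suffix as a fixed or a random block, the arrays sharing a label suffix alone, and leaving out each array in turn. The level of Eif2s3y, a Y-linked gene, as a covariate, and leaving out scramble 3, miR-34a 3 and miR-324 1 together, were added after seeing the data. In both suffix blocks the arrays without a suffix formed 1 level, although the labels do not say that they share a batch. Array numbers are those of the labels except in scramble, where the labels repeat a number and arrays were numbered in order.

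The calculations were tested on simulated data with the spread of the real genes, over 19572 genes with 50 genes seeded at each fold. In simulated miR-21 against scramble, 14% of 2-fold changes, 76% of 4-fold changes, 98% of 8-fold changes and 100% of 16-fold changes were called. The same shares were 18%, 88%, 96% and 98% for miR-34a, and 26%, 86%, 98% and 98% for miR-324. False calls made up 3.29%, 6.75% and 4.29% of calls in these comparisons, and the shifted list was called each time with 0 other lists. Genes and arrays were drawn independently, without correlated genes or cultures that differ within a group. These shares therefore check the calculations and do not give the rate of false gene or list calls in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.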

Results

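Transcript levels of cultured mouse trigeminal ganglion (TG) neurons were measured on 12 arrays, 3 for each of miR-21, miR-34a, miR-324 and scramble. The series title names neural reprogramming in head and neck cancer, and each comparison asks which transcripts differ after transfection of 1 miRNA from those after scramble. miR-21 and miR-34a are widely studied in tumours, the first mostly as a growth-promoting and the second as a p53-induced miRNA. The labels of 4 arrays, scramble 1 and 2 and miR-34a 1 and 2, carry a shared suffix, called suffix A here. Scramble 3 and miR-324 2 share another, called suffix B, and the other 6 arrays carry none.

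The arrays differed in cell type markers within groups as well as between them. Macrophage markers had a median signal of 8.76, 8.64 and 4.81 in scramble 1, 2 and 3 and of 9.20, 8.79 and 4.72 in miR-34a 1, 2 and 3, against 5.24 to 5.44 in the miR-21 arrays and 4.49 to 4.70 in the miR-324 arrays. Pan-neuronal genes had a median of 12.16 to 13.21 in scramble, 10.91 to 11.26 in miR-21, 13.00, 12.74 and 9.21 in miR-34a 1, 2 and 3, and 9.22, 11.93 and 11.80 in miR-324 1, 2 and 4. Prl, the pituitary hormone prolactin, stood at 14.92 in scramble 3 and 14.98, 14.26 and 15.17 in the miR-324 arrays, and between 3.37 and 4.83 in the other 8 arrays. Eif2s3y, carried on the Y chromosome, stood at 7.26, 7.09 and 7.85 in the miR-21 arrays, 8.53 in miR-34a 3, 7.88 in miR-324 1 and 5.13 in miR-324 4, and at 2.96 or lower in the other 6. Probes for olfactory and vomeronasal receptors, a guide to the floor of the arrays, had medians of 3.51 to 4.12.

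Arrays of different groups that share a suffix correlated at 0.987 to 0.994 across genes (5 pairs), and arrays of 1 group without a shared suffix at 0.951 to 0.991 (10 pairs); genes are not independent replicates. Scramble 3 differed by over 2-fold from the mean of scramble 1 and 2 in 12.5% of probes, and miR-34a 3 from miR-34a 1 and 2 in 18.5%.

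**Figure D1:**
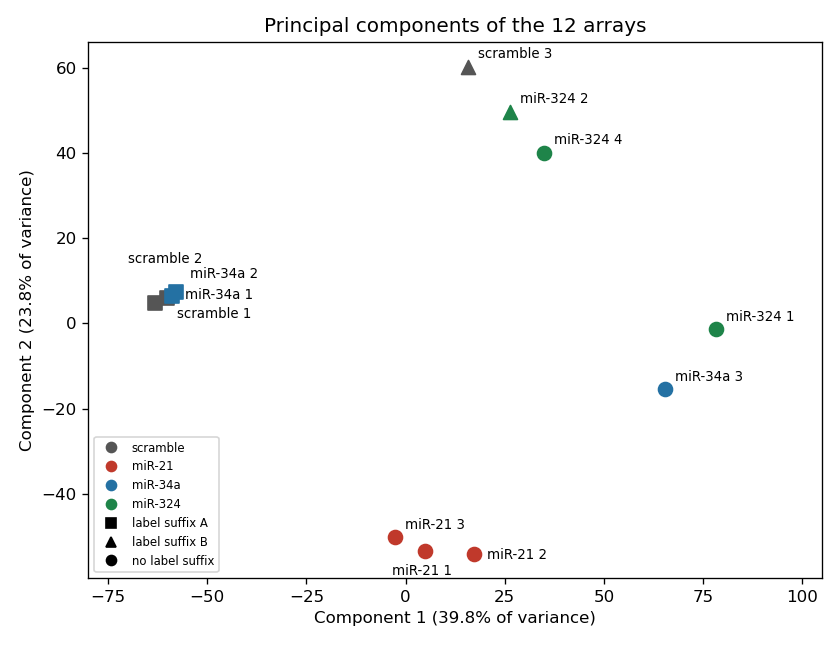
Principal components of the 12 arrays, with component 1 (39.8% of variance) on the x axis and component 2 (23.8%) on the y axis, both without units; colour gives the group, and squares, triangles and circles mark label suffix A, suffix B and no suffix. Scramble 1 and 2 and miR-34a 1 and 2 lie together between −63.28 and −57.83 on component 1, while scramble 3 lies at 15.78 and miR-34a 3 at 65.53.

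**Figure D2:**
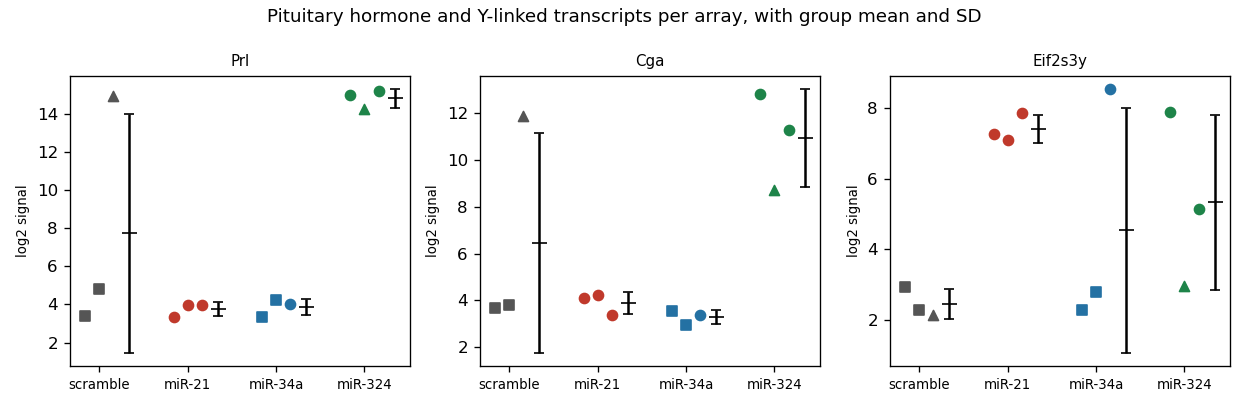
Log2 signal (y axis) of Prl, Cga and Eif2s3y in each array, by group on the x axis; squares mark suffix A, triangles suffix B and circles no suffix, and the black dash and bar give the mean ± SD of 3 arrays. Prl and Cga (a subunit of pituitary hormones) are high in scramble 3 (14.92 and 11.85) and in each miR-324 array, and Eif2s3y in each miR-21 array, in miR-34a 3 and in miR-324 1.

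After miR-21, 5 of 26 measured genes of the interferon response fell and 0 rose. Irf9, a subunit of the transcription factor that interferon activates, fell by 2.71 ± 0.28 on the log2 scale (5.80 ± 0.17 against 8.51 ± 0.39, SD, n = 3; adjusted p = 0.0035). Oasl2, an antiviral protein induced by interferon, fell by 3.70 ± 0.41 (6.84 ± 0.02 against 10.54 ± 0.60; adjusted p = 0.0053), a 13.0-fold difference. Stat2, the partner of Irf9, fell by 2.04 ± 0.36 (adjusted p = 0.025), and Xaf1 and Ifit1 fell as well (−2.45 and −3.43; adjusted p = 0.020 and 0.040). The other 21 did not pass; adjusted over the list alone 14 fell, and 22 were lower in the mean. The list's median difference was −2.03 (camera adjusted p = 1.84e-15; adjusted p = 0.45 with an estimated correlation), and −1.09 without scramble 3. The list's median signal was 5.89, 5.72 and 5.31 in the miR-21 arrays and 6.88, 7.43 and 8.98 in scramble 1, 2 and 3. Outside this list Sting1, an adaptor of the cytosolic DNA pathway, Ifi207 and Lgals3bp differed by −3.88, −3.60 and −3.53 (adjusted p = 0.031, 0.020 and 0.014). In the 6 fits without 1 array each, Irf9 and Oasl2 passed throughout, Lgals3bp only without scramble 2, scramble 3 or miR-21 3, Ifi207 only without scramble 3, and Stat2, Xaf1 and Ifit1 only without scramble 1. Sting1 passed in none (adjusted p = 0.051 to 0.13). It stood at 7.29 in miR-34a 3 and 8.31 in miR-324 1, against 4.96 to 7.56 in the miR-21 arrays. Macrophage markers had a median difference of −1.67 in the same arrays (camera adjusted p = 2.48e-05; adjusted p = 0.60 with an estimated correlation). All 17 were lower in the mean, and 0 passed over all genes or adjusted over the list alone. Leaving out scramble 1, 2 or 3 moved the macrophage median to −1.10, −0.94 or −2.99, and it was 0.69 with the label suffix as a fixed block and 0.15 with the level of Eif2s3y as a covariate. Endothelial markers were also lowest in the miR-21 arrays, with a median signal of 8.76, 8.23 and 8.88 against 9.36, 9.80 and 11.53 in scramble 1, 2 and 3, the same order over the scramble arrays as in the interferon list.

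After miR-21, 2 of 14 myelinating Schwann cell markers, Mbp and Cldn19, rose and 0 fell. Mbp, the myelin basic protein, rose by 3.90 ± 0.82 (14.41 ± 0.19 against 10.50 ± 0.51, SD, n = 3; adjusted p = 0.046), and Cldn19, a tight junction protein of Schwann cells, by 2.88 ± 0.45 (adjusted p = 0.017). The other 12 did not pass; adjusted over the list alone 10 rose, and all 14 were higher in the mean. The list's median difference was 1.41 (camera adjusted p = 6.2e-08; adjusted p = 0.45 with an estimated correlation), and its median signal was also 9.14 in miR-34a 3, against 6.92 to 7.36 in scramble. Outside this list Pmp2, a lipid-binding protein of peripheral myelin, stood at 12.86 ± 0.19 against 7.35 ± 2.70 in scramble, a difference of 5.51 ± 1.02 (adjusted p = 0.028). Hspg2, the basement membrane proteoglycan perlecan, rose by 3.75 ± 0.59 (13.85 ± 0.25 against 10.10 ± 0.15; adjusted p = 0.017), and Col1a2, a chain of type I collagen, by 4.45 ± 0.83 (15.31 ± 0.19 against 10.86 ± 2.18; adjusted p = 0.029). Col5a2, another fibrillar collagen chain, Lox, which crosslinks collagen, and the tenascin Tnn rose by 3.33, 4.30 and 4.93 (adjusted p = 0.016, 0.041 and 0.042), and the cadherin Cdh6 by 4.10 (adjusted p = 0.023). In miR-34a 3 and miR-324 1, the other arrays with the highest Eif2s3y, Hspg2 stood at 13.00 and 13.23, Mbp at 14.01 and 12.94, Lox at 10.70 and 12.59 and Col1a2 at 11.12 and 10.22. In the 6 fits without 1 array each, Mbp and Lox passed in none (adjusted p = 0.091 to 0.15 and 0.064 to 0.16), nor did Cspg4, a mural cell gene given next (0.055 to 0.14). Cldn19 passed only without scramble 1, Tnn only without miR-21 2, Col1a2 only without scramble 1 or 3 and Hspg2 only without scramble 2 or 3. Pmp2 and Cdh6 passed without any scramble array and failed without any miR-21 array, and Col5a2 failed without miR-21 1 or 3. Tnn varied most between the miR-21 arrays (8.57 ± 2.83). Of 16 fibroblast markers 1 rose (Col1a2), and 4 rose and 1 fell adjusted over the list alone (median 0.21, camera adjusted p = 0.46). Of 12 mural cell markers 1 rose, the pericyte proteoglycan Cspg4 (2.65, adjusted p = 0.029), and 3 rose and 1 fell adjusted over the list alone (median 0.19, camera adjusted p = 0.70). Satellite glia markers had a median of 0.22 (camera adjusted p = 0.69), with none past over all genes and 5 up and 2 down adjusted over the list alone. Without scramble 3 or scramble 2 the median was −0.07 or 0.68 for mural cell and −0.08 or 0.89 for satellite glia markers, again with no call.

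After miR-21, 3 of 19 cholesterol synthesis genes fell and 0 rose. Insig1, which holds back sterol synthesis and is itself induced when sterols are low, fell by 1.85 ± 0.28 (10.00 ± 0.17 against 11.85 ± 0.12, SD, n = 3; adjusted p = 0.016). The enzymes Msmo1 and Idi1 fell as well (−1.89 ± 0.36 and −2.07 ± 0.43; adjusted p = 0.032 and 0.044). In the 6 fits without 1 array each, Idi1 passed in none (adjusted p = 0.069 to 0.15), Msmo1 only without scramble 3 and Insig1 only without a scramble array. The other 16 did not pass; adjusted over the list alone 15 fell, and all 19 were lower in the mean. The list's median difference was −1.39 (camera adjusted p = 1.84e-15; adjusted p = 0.45 with an estimated correlation). Its median signal was 9.58 to 10.12 in the miR-21 arrays and 11.44 to 11.98 in scramble, but also 10.11 in miR-34a 3 and 9.51 in miR-324 1, the other arrays with the highest Eif2s3y. With the label suffix as a fixed block its median was 0.00 (camera adjusted p = 0.41), and with the Eif2s3y level as a covariate it was −0.11 (camera adjusted p = 0.075).

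Neuronal genes had lower means after miR-21 without a single gene past the threshold. Pan-neuronal genes had a median difference of −1.27, with 25 of 26 lower in the mean and 0 past over all genes or adjusted over the list alone (camera adjusted p = 5.99e-07; adjusted p = 0.61 with an estimated correlation). Snap25, a synaptic vesicle fusion protein, stood at 14.17 ± 0.35 against 15.74 ± 0.65 (SD, n = 3; adjusted p = 0.36). Sensory neuron genes had a median of −0.75, with 23 of 31 lower and 0 past by either adjustment (camera adjusted p = 0.025; adjusted p = 0.78 with an estimated correlation). The sensory call was absent without miR-21 2 (median −0.58, camera adjusted p = 0.16), without scramble 1 (−0.62, 0.25) or without scramble 2 (−0.47, 0.16), and the median was −1.28 without scramble 3. With the label suffix as a fixed block both medians were above 0 (0.98 for pan-neuronal and 1.53 for sensory neuron genes), and so they were with the Eif2s3y covariate (1.16 and 1.23). Genes of nerve injury and regeneration went both ways. Hspb1, a small heat shock protein of injured neurons, and Gadd45a, a stress-induced growth arrest gene, fell (−1.81 and −1.44; adjusted p = 0.016 and 0.044). The cytokine Lif rose by 1.55 (adjusted p = 0.044). Lif passed in none of the 6 fits without 1 array (adjusted p = 0.094 to 0.17), Gadd45a only without scramble 1, and Hspb1 in all but those without miR-21 1 or 2. Of 27 such genes 1 rose, 2 fell and 24 did not pass, with 3 up and 12 down adjusted over the list alone (median −0.76, camera adjusted p = 2.54e-05; adjusted p = 0.45 with an estimated correlation). With the Eif2s3y covariate the nerve injury and regeneration genes had a median of 0.03 and were not called. Adrenergic and sympathetic genes had a median of −0.12 and cholinergic genes of −0.25 (camera adjusted p = 0.11 and 0.074), and without miR-21 2 both were called (−0.16 and −0.31, camera adjusted p = 0.034 and 0.046). Th and Dbh, the enzymes of noradrenaline synthesis, differed by 0.36 ± 0.45 and −0.41 ± 0.41 (adjusted p = 0.72 and 0.64). Axon growth and guidance genes (median −0.10) and progenitor and pluripotency genes (0.23) were not called (camera adjusted p = 0.34 and 0.60).

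Cell cycle genes had a median of 0.92 after miR-21, with 28 of 29 higher in the mean and 0 past by either adjustment (camera adjusted p = 0.0016; adjusted p = 0.77 with an estimated correlation). The median was 1.38 without scramble 2, and the call was absent without scramble 3 (0.27, camera adjusted p = 0.61). In scramble 3 Mki67, a marker of dividing cells, stood at 7.02 against 10.93 and 10.49 in scramble 1 and 2 and 12.28 to 12.63 after miR-21. Endothelial markers had a median of −0.89, with 13 of 14 lower (camera adjusted p = 5.62e-04; adjusted p = 0.61 with an estimated correlation), and −0.13 without scramble 3 (camera adjusted p = 0.11) or −1.34 without scramble 1. Ly6c1, a surface protein of endothelial cells and monocytes, was the only endothelial marker to fall, by 4.78 ± 0.58 (adjusted p = 0.0097), over all genes and adjusted over the list alone (1 of 14). Inflammatory and NF-kB genes had a median of −0.62, with 0 past over all genes and 1 up and 4 down adjusted over the list alone (camera adjusted p = 5.29e-04; adjusted p = 0.30 with an estimated correlation), and −0.24 without scramble 3. Reported targets of miR-21 were not lower: 2 of 44 rose (Jag1, a Notch ligand, by 2.43 and Satb1, a chromatin organiser, by 1.36; adjusted p = 0.029 and 0.023) and 0 fell, with 6 up and 1 down adjusted over the list alone (median 0.26, camera adjusted p = 0.25). Pdcd4, a translation inhibitor reported as a miR-21 target, differed by −0.13 ± 0.25 (adjusted p = 0.83). Reported targets of miR-34a had a median of 0.27 after miR-21, with 4 of 42 past, all higher (Fut8 1.45, Fndc3b 1.05, Jag1 2.43, Vcl 1.49; adjusted p = 0.023, 0.028, 0.029 and 0.048), and 7 adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.55 with an estimated correlation). Without 1 array, Jag1, Satb1, Fndc3b and Vcl passed in none of the 6 fits (adjusted p = 0.055 to 0.13, 0.059 to 0.088, 0.069 to 0.13 and 0.065 to 0.16) and Fut8 only without scramble 2. The list call was absent without miR-21 3 (0.23, camera adjusted p = 0.065) or scramble 3 (0.21, 0.17). Cdk6 and Sirt1, on the same list, differed by 0.77 ± 0.75 and 0.04 ± 0.26 (adjusted p = 0.63 and 0.96).

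The other lists were not called after miR-21. Of 26 p53 target genes 1 fell (Gadd45a, as above), with 4 up and 2 down adjusted over the list alone (median 0.27, camera adjusted p = 0.66), and of 19 immediate early genes 1 fell (Ier3, by 2.50, adjusted p = 0.025, passing only without scramble 1 when 1 array was left out), with 5 up and 2 down adjusted over the list alone (median 0.26, camera adjusted p = 0.69). Integrated stress response genes had a median of −0.10 (camera adjusted p = 0.070; 1 up and 1 down adjusted over the list alone) and were called without miR-21 1 (−0.19, 0.040), miR-21 3 (−0.23, 0.027) or scramble 1 (−0.14, 0.027). Oxidative phosphorylation genes had a median of −0.02 (camera adjusted p = 0.35), and −0.19 without scramble 3 (0.019). T and mast cell markers had a median of 0.10, a mean of −0.09 and a test in the lower direction (camera adjusted p = 0.61), and reported miR-324 targets a median of −0.01 (0.40).

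In all 204 of 19572 genes (1.04%) passed the threshold in limma, 134 higher and 70 lower after miR-21, against a median of all genes of 0.13, and all were among the 5012 genes (25.6%) whose groups did not overlap, where chance gives 10%. The median of all genes was 0.03 after quantile normalization again and 0.13 with each array centred on its median. The remaining named falls were the matrix protease Mmp3 (−3.91, adjusted p = 0.029) and the calmodulin regulator Pcp4 (−3.38, adjusted p = 0.029). Without 1 array Mmp3 passed only without scramble 2 or 3 and Pcp4 in no fit (adjusted p = 0.067 to 0.13). Pcp4 was as low in miR-34a 3 and miR-324 1 (6.89 and 6.76) as after miR-21 (6.57 to 6.78). Mmp3 was not, at 8.20 and 9.51 against 4.81 to 5.93. The count was 60, 81 or 78 without scramble 1, 2 or 3 and 11, 19 or 33 without miR-21 1, 2 or 3; of the named genes Irf9, Oasl2 and Ly6c1 passed in each of these fits. With the label suffix as a fixed block 684 genes passed, 78 of them among the 204, and with the Eif2s3y covariate 89, 25 of them among the 204. Of these 89 genes 21 were higher and 68 lower. Eif2s3y itself separated the groups, at 7.09 to 7.85 in the miR-21 arrays and 2.13 to 2.93 in scramble. The covariate is fitted on differences within groups, which were largest in miR-34a and miR-324. It therefore cannot tell cultures with Y-linked transcripts from miR-21. With the suffix as a random block 34 genes passed, all of them among the 204. Of the named genes these included Irf9, Oasl2, Xaf1, Lgals3bp, Ly6c1, Col1a2 and Col5a2 and not Pmp2, Mbp, Hspg2 or Insig1. Both suffix blocks treat the arrays without a suffix, all miR-21 arrays among them, as 1 level. The labels do not say that these arrays share a batch, and no scramble array is among them.

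**Figure D3:**
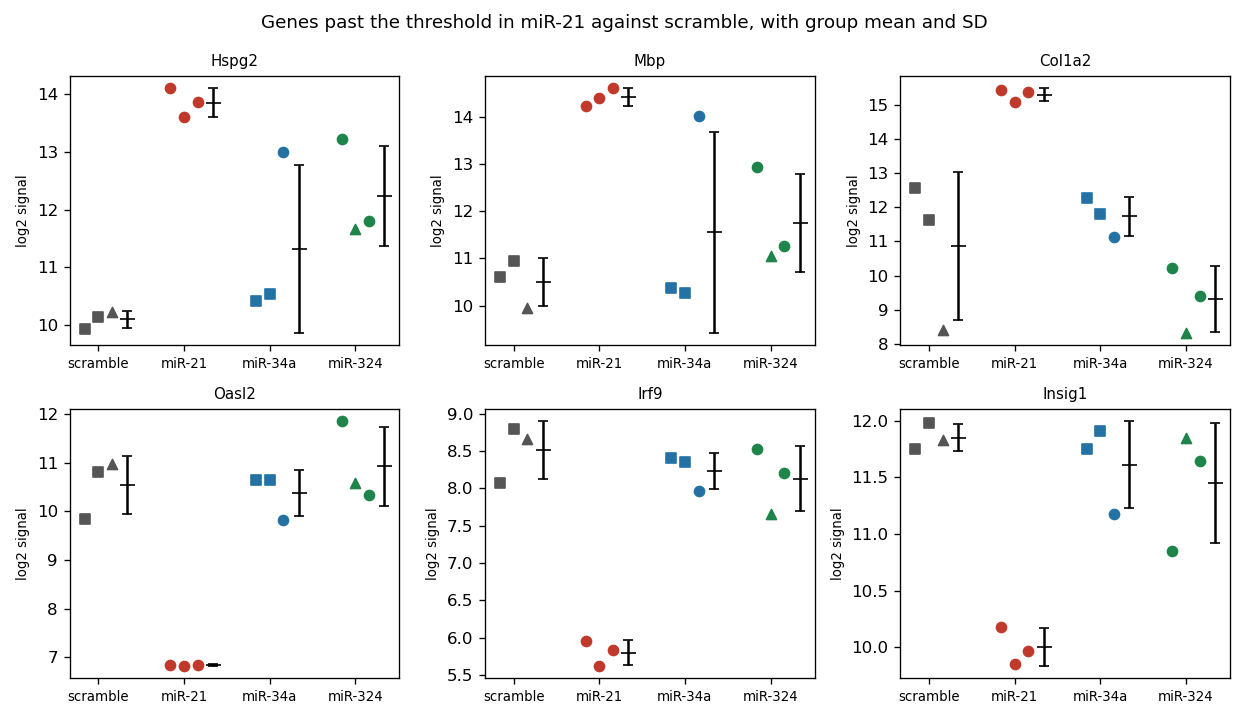
Log2 signal (y axis) of 6 genes past the threshold in miR-21 against scramble, for each array by group on the x axis; squares mark suffix A, triangles suffix B and circles no suffix, and the black dash and bar give the mean ± SD of 3 arrays. The miR-21 arrays lie above all scramble arrays for Hspg2 (13.85 ± 0.25 against 10.10 ± 0.15), Mbp and Col1a2, and below them for Oasl2, Irf9 and Insig1 (10.00 ± 0.17 against 11.85 ± 0.12).

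After miR-34a no gene passed the threshold. The genes with the smallest unadjusted p included Mettl7b, a lipid droplet protein (1.01 ± 0.27), Bicdl2 (0.88 ± 0.25), the helicase Dhx16 (0.85 ± 0.26), Pcdhb19 (0.83), Rgs12 (0.83), Echdc2 (0.71), Usp46 (0.69) and Svs1 (0.63) among those with higher means. Among those with lower means were the histone gene H4c9 (−1.12 ± 0.31), Pkhd1l1 (−1.19 ± 0.35), the growth factor Ereg (−0.91 ± 0.27), Atxn7l2 (−0.78 ± 0.21), Ssxb10 (−0.95), Apof (−0.90), Zmynd12 (−0.80) and Ifnab (−0.65). The reported miR-34a targets Cdk6, a cell cycle kinase, and Sirt1, a deacetylase, differed by −0.34 ± 0.75 and 0.19 ± 0.26, and Th, Dbh and Pdcd4 by −0.40 ± 0.45, −0.40 ± 0.41 and −0.16 ± 0.25; the adjusted p was 1.00 for each of these genes. The limma count was 0 of 19572, with 286 genes (1.46%) at an unadjusted p under 0.05, 32 of them at least 2-fold different, and 1135 genes (5.8%) without overlap between groups, where chance gives 10%. The count was 0 without any 1 of the 6 arrays.

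Neuronal genes had lower means after miR-34a, and Schwann cell markers higher ones, in the list test. Pan-neuronal genes had a median of −0.82, with 25 of 26 lower in the mean (camera adjusted p = 2.48e-07; adjusted p = 0.61 with an estimated correlation). Sensory neuron genes had −0.48, with 25 of 31 lower (0.0046; adjusted p = 0.77 with an estimated correlation), and nerve injury genes −0.16 (0.0011; adjusted p = 0.45 with an estimated correlation). Myelinating Schwann cell markers had a median of 0.70, with 12 of 14 higher (camera adjusted p = 1.83e-04; adjusted p = 0.45 with an estimated correlation). Array miR-34a 3 stood apart in these lists. Tubb3, a neuronal tubulin, stood at 14.87, 14.80 and 10.15 in miR-34a 1, 2 and 3 and at 14.51, 15.18 and 12.95 in scramble. Within suffix A, miR-34a 1 and 2 differed from scramble 1 and 2 by 0.03 for pan-neuronal, 0.05 for sensory neuron, 0.07 for nerve injury and 0.02 for Schwann cell genes. Without miR-34a 3 the medians were 0.18 for pan-neuronal (camera adjusted p = 0.022), 0.38 for sensory neuron (4.93e-05), 0.06 for nerve injury (0.59) and 0.12 for Schwann cell genes (0.21). Without miR-34a 1 or 2 they were −1.50 or −1.29 for pan-neuronal, −1.25 or −1.17 for sensory neuron and −0.45 or −0.31 for nerve injury genes, and 1.06 for Schwann cell genes without miR-34a 2. The sensory call was also absent without scramble 1 (−0.27, camera adjusted p = 0.38) or scramble 2 (−0.21, 0.20), and its median was −1.07 without scramble 3. Nerve injury genes had −0.31 without scramble 1 and −0.27 without scramble 3. With the Eif2s3y covariate pan-neuronal and sensory neuron genes had medians above 0 (0.13 and 0.32).

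Interferon response genes (median −0.27, camera adjusted p = 0.0073; adjusted p = 0.77 with an estimated correlation), cholesterol synthesis genes (−0.27, 0.023; adjusted p = 0.78 with an estimated correlation) and inflammatory genes (−0.20, 0.034; adjusted p = 0.45 with an estimated correlation) were called lower after miR-34a. No member of these lists or of any other list passed over all genes, and 0 passed adjusted over the list alone. Within suffix A the shifts were 0.09, 0.00 and −0.14. Interferon genes had a median of −0.65 without scramble 1, 0.22 without scramble 3 (camera adjusted p = 0.086) and −0.20 without miR-34a 1 (0.074). Cholesterol genes had one of 0.33 without miR-34a 3 (0.0022), −0.21 without scramble 1 (0.33) and −0.04 without scramble 2 (0.48). It was −0.48 without scramble 3 or miR-34a 1 and −0.49 without miR-34a 2. Inflammatory genes were not called without miR-34a 1 (−0.41, 0.12), miR-34a 3 (−0.21, 0.080), scramble 1 (−0.04, 0.18) or scramble 3 (−0.11, 0.49), and had −0.40 without scramble 2 and −0.36 without miR-34a 2.

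The remaining lists were not called after miR-34a. Reported miR-34a targets had a median of −0.02, a mean of 0.03 and a test in the lower direction (42 genes, camera adjusted p = 1.00), and 0.19 without miR-34a 3 (0.026). The median was −0.07 for cell cycle genes, −0.09 for macrophage and 0.17 for endothelial markers, 0.13 for p53 targets, −0.10 for axon growth and guidance genes and −0.12 for fibroblast markers. Without miR-34a 3 each of these was called on the other side of 0 (0.82, 1.06, −0.63, −0.21, 0.19 and 0.32). That fit still holds scramble 3, which differed from scramble 1 and 2. Within suffix A, miR-34a 1 and 2 differed from scramble 1 and 2 by 0.02, −0.19, 0.06, −0.01, 0.11 and −0.03 in the same order. Reported miR-34a targets differed by −0.01 there. Without scramble 3, miR-34a 1 or miR-34a 2 calls were made for cell cycle genes (−0.76, −0.46 or −0.53), macrophage markers (−1.21, −0.66 or −0.75), endothelial markers (1.07, 0.67 or 0.71) and p53 targets (0.31, 0.36 or 0.38). Fibroblast markers were called without scramble 3 (−0.43) or miR-34a 2 (−0.32), axon genes without miR-34a 2 (−0.23), oxidative phosphorylation genes without scramble 3 (−0.12), and immediate early genes without scramble 1 (−0.08) or miR-34a 3 (−0.22). The median was −0.06 for adrenergic genes, 0.24 for satellite glia, −0.03 for T and mast cell markers, −0.01 for integrated stress response, −0.04 for oxidative phosphorylation genes, 0.13 for reported miR-21 targets and −0.08 for reported miR-324 targets. Median, mean and test differed in sign for cholinergic genes (0.08, −0.02, higher), progenitor genes (−0.01, 0.02, lower), mural cell markers (−0.04, 0.29, lower) and immediate early genes (0.06, −0.05, lower), none of them called.

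After miR-324 no gene passed the threshold either, but groups of endothelial and macrophage genes stood apart from scramble. Endothelial markers had a median difference of 2.37, with all 14 higher in the mean, 0 past over all genes and 12 higher adjusted over the list alone (camera adjusted p = 8.12e-08; adjusted p = 0.45 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, stood at 16.14 ± 0.59 against 13.43 ± 1.88 (SD, n = 3; adjusted p = 0.31). Macrophage markers had a median of −2.59, with all 17 lower, 0 past over all genes and 11 lower adjusted over the list alone (camera adjusted p = 6.23e-10; adjusted p = 0.45 with an estimated correlation). Csf1r, the receptor that macrophages need to survive, stood at 4.63 ± 0.51 against 7.21 ± 2.58 (adjusted p = 0.35). Scramble 3 lay on the side of the miR-324 arrays in both lists, with Cdh5 at 15.59 against 12.41 and 12.28 in scramble 1 and 2, and Csf1r at 4.24 against 8.76 and 8.64. Within suffix B, miR-324 2 differed from scramble 3 by 0.42 in endothelial and −0.49 in macrophage markers, 1 array against 1; macrophage markers in scramble 3 lay only 1.08 above the floor probes of that array, too near for a fall of the size between the groups. Prl and Cga, high in all miR-324 arrays, were also high in scramble 3.

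Neuronal, cycling and metabolic genes had lower means after miR-324. The median was −1.56 for pan-neuronal genes, with all 26 lower (camera adjusted p = 5.38e-09; adjusted p = 0.55 with an estimated correlation), and −1.69 for sensory neuron genes, with 29 of 31 lower (5.36e-09; adjusted p = 0.50 with an estimated correlation). Tac1, the precursor of the pain peptide substance P, stood at 10.30 ± 1.37 against 13.11 ± 1.11 (SD, n = 3; adjusted p = 0.32). Cell cycle genes had a median of −1.06, with all 29 lower (camera adjusted p = 2.75e-08; adjusted p = 0.60 with an estimated correlation), and oxidative phosphorylation genes −0.29, with 26 of 31 lower (2.59e-05; adjusted p = 0.50 with an estimated correlation). Cholesterol synthesis genes had a median of −0.96, with all 19 lower and 3 lower adjusted over the list alone (camera adjusted p = 6.66e-10; adjusted p = 0.45 with an estimated correlation). None of these lists had a member past over all genes, and apart from the sterol genes 0 members passed adjusted over the list alone. Within suffix B the differences were −0.29 for pan-neuronal, −0.08 for sensory neuron, 0.05 for cell cycle, 0.01 for oxidative phosphorylation and 0.00 for cholesterol synthesis genes. Leaving out miR-324 1 moved the medians to −0.80 for pan-neuronal, −1.06 for sensory neuron and −0.59 for cholesterol synthesis genes, and cell cycle genes moved to −1.85 without scramble 3 and −0.67 without scramble 1. With the label suffix as a fixed block the medians of pan-neuronal, sensory neuron and cell cycle genes were above 0 (0.31, 0.17 and 0.40).

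Interferon response genes had a higher mean after miR-324, with a median of 1.10 and 22 of 26 higher (camera adjusted p = 1.56e-04; adjusted p = 0.63 with an estimated correlation), and 0.65 without miR-324 1; within suffix B the difference was −0.68. The endothelial markers given above had higher means in the same arrays. Targets of p53 had a median of 0.60 (camera adjusted p = 0.0051; adjusted p = 0.65 with an estimated correlation), and 0.01 within suffix B. Fibroblast markers (−0.85, camera adjusted p = 0.0019), satellite glia markers (−0.64, 0.012) and mural cell markers (−0.16, 0.029) were called lower, each with adjusted p = 0.45 with an estimated correlation, and differed by 0.03, 0.25 and −0.21 within suffix B. Nerve injury genes had a median of −0.44 (0.022; adjusted p = 0.55 with an estimated correlation). Reported miR-324 targets had a median of −0.42, with 10 of 15 lower (camera adjusted p = 0.048; adjusted p = 0.45 with an estimated correlation), and −0.13 within suffix B. In these lists 0 members passed over all genes or adjusted over the list alone. The miR-324 target call was absent without miR-324 1 (−0.20, camera adjusted p = 0.16), miR-324 2 (−0.37, 0.051), scramble 1 (−0.42, 0.075) or scramble 3 (−0.39, 0.088). Mural cells were not called without miR-324 2 (−0.30, 0.11) or scramble 1 (−0.25, 0.075), nerve injury genes without miR-324 1 (−0.37, 0.39) or scramble 3 (−0.45, 0.15), and satellite glia without miR-324 1 (−0.87, 0.11). Other single arrays moved called medians, satellite glia to −1.32 without scramble 3 and −0.26 without scramble 2, mural cells to −0.58 without miR-324 1, −0.53 without scramble 3, −0.31 without scramble 2 and −0.26 without miR-324 4, and fibroblasts to −0.52 without scramble 2. With the label suffix as a fixed block p53 targets had −0.08, fibroblast markers 0.15 and nerve injury genes 0.20.

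The lists not called after miR-324 had medians of 0.07 for adrenergic genes, −0.08 for cholinergic genes, 0.18 for progenitor genes, 0.25 for myelinating Schwann cell markers, −0.02 for T and mast cell markers, 0.31 for immediate early genes and 0.23 for reported miR-21 targets. Immediate early genes were called without scramble 3 (0.53, camera adjusted p = 0.012). Axon growth and guidance genes had a median of −0.47 (camera adjusted p = 0.14), with 3 higher adjusted over the list alone. Median, mean and test differed in sign for inflammatory genes (0.17, −0.01, higher; 1 higher adjusted over the list alone), integrated stress response genes (0.04, −0.09, lower; 1 lower adjusted over the list alone) and reported miR-34a targets (0.04, −0.19, lower).

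Single genes with the smallest unadjusted p after miR-324 included Notch4, an endothelial Notch receptor (1.84 ± 0.28; 7.05 ± 0.27 against 5.21 ± 0.50, SD, n = 3), the phosphatase Ctdsp1 (2.23 ± 0.40), the synaptic scaffold Shank3 (2.03 ± 0.39), the histone methyltransferase Kmt2d (1.60 ± 0.33), Dgat1, which makes triglycerides (1.40 ± 0.27), Phactr4 (1.62), Retsat (1.22) and Slc17a3 (1.28). Lower means were found for the phospholipase Plcd4 (−2.33 ± 0.42), Tmem74 (−2.20 ± 0.48), the thiopurine methyltransferase Tpmt (−1.26 ± 0.23), H4c9 (−1.45 ± 0.31), Rab39 (−1.44), Rab35 (−1.38), Pla2g6 (−1.12) and the DNA repair gene Aptx (−1.07). Each of these had an adjusted p of 0.31. Th differed by −0.81 ± 0.45 (adjusted p = 0.40), Dbh by −0.52 ± 0.41 (0.54), Cdk6 by −1.28 ± 0.75 (0.42), Sirt1 by 0.42 ± 0.26 (0.45) and Pdcd4 by 0.22 ± 0.25 (0.70). The limma count was 0 of 19572, with 2877 genes (14.7%) at an unadjusted p under 0.05, 1146 of them at least 2-fold different (449 higher and 697 lower), against a median of all genes of 0.09 that became 0.16 with each array centred on its median. Groups did not overlap for 3892 genes (19.9%), where chance gives 10%. The count was 383 without scramble 3 and 0 without any 1 of the other arrays. Without scramble 3 no scramble array had the Prl level of the miR-324 arrays, so a difference between cultures cannot be told apart from miR-324 there.

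**Figure D4:**
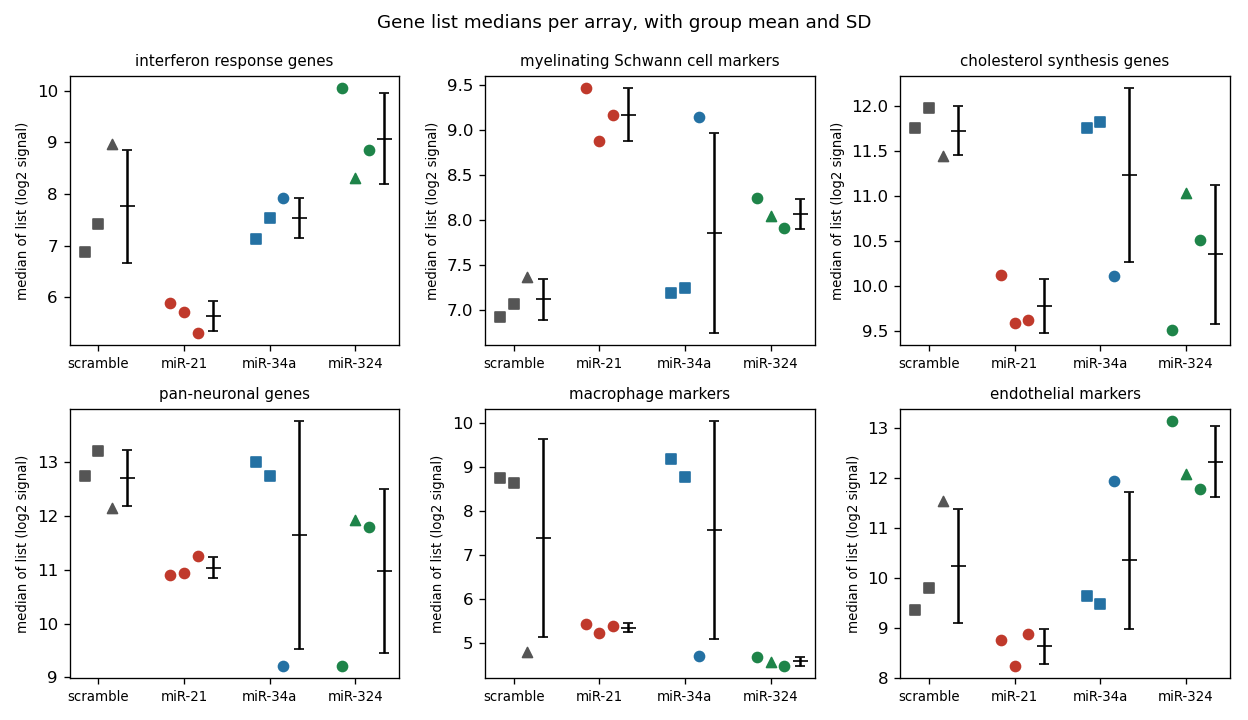
Median log2 signal (y axis) of 6 gene lists in each array, by group on the x axis; squares mark suffix A, triangles suffix B and circles no suffix, and the black dash and bar give the mean ± SD of 3 arrays. Interferon response genes are lowest in the miR-21 arrays (5.31 to 5.89), and in macrophage and endothelial markers scramble 3 (4.81 and 11.53) lies nearer to the miR-324 arrays than to scramble 1 and 2.

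Between miRNAs, Oasl2 and other genes of innate immunity or endothelium were higher after miR-34a than after miR-21. Oasl2 was higher by 3.53 ± 0.41 (adjusted p = 0.0066), Lgals3bp by 3.38 ± 0.53 (adjusted p = 0.035) and Ly6c1 by 4.33 ± 0.58 (adjusted p = 0.017). Selp, an adhesion molecule of activated endothelium, was higher by 3.89 ± 0.52 (adjusted p = 0.017). The matrix genes Lama2 and Efemp1, the clotting initiator F3 and the junction protein Plekha7 were lower after miR-34a (−2.43, −2.23, −2.45 and −2.02; adjusted p = 0.045, 0.024, 0.045 and 0.0084). The interferon list had a median of 1.57, with 2 of 26 past over all genes and 11 adjusted over the list alone, all higher after miR-34a (camera adjusted p = 2.28e-14; adjusted p = 0.37 with an estimated correlation). Endothelial markers had a median of 1.24, with all 14 higher in the mean and 1 past (camera adjusted p = 4.8e-06; adjusted p = 0.41 with an estimated correlation), and macrophage markers 1.42, with all 17 higher and 0 past (2.88e-05; adjusted p = 0.48 with an estimated correlation). The cholesterol list had 1.10, with 0 past over all genes and 10 higher adjusted over the list alone (9.59e-15; adjusted p = 0.37 with an estimated correlation), but its signal in miR-34a 3 (10.11) lay within the miR-21 range (9.58 to 10.12), against 11.75 and 11.82 in miR-34a 1 and 2. In all 31 genes passed in limma, 17 higher and 14 lower after miR-34a. The count was 537 without miR-34a 3, 2 without miR-34a 1 or 2, 6 without miR-21 1 or 3, and 3 without miR-21 2. Each of the 8 genes named here passed without miR-34a 3 and failed without miR-21 2, miR-34a 1 or miR-34a 2, where Oasl2 had adjusted p = 0.056, 0.062 and 0.051.

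Between miR-21 and miR-324, 17 of 26 interferon response genes and 7 of 14 endothelial markers were lower after miR-21. Pmp2 was higher by 6.78 ± 1.02 (adjusted p = 0.0080), Col1a2 by 6.00 ± 0.83 (0.0052), the smooth muscle actin Actg2 by 5.64 ± 1.17 (0.028) and the matrix protein Postn by 5.39 ± 0.86 (0.0091). Prl was lower after miR-21 (−11.04 ± 2.09; 3.77 ± 0.34 against 14.80 ± 0.48, SD, n = 3; adjusted p = 0.019), as were the endothelial Notch ligand Dll4 (−6.68 ± 1.56, 0.045) and the interferon-induced genes Ifit3b (−5.76 ± 1.02, 0.014) and Cmpk2 (−5.70 ± 1.00, 0.013). No interferon gene was higher over all genes, and 20 were lower adjusted over the list alone (median −2.84, camera adjusted p = 1.54e-26; adjusted p = 0.31 with an estimated correlation, 0.031 by fry). Of the endothelial markers 13 were lower adjusted over the list alone (median −3.43, camera adjusted p = 4.95e-16; adjusted p = 0.31 with an estimated correlation). Of 29 cell cycle genes 2 were higher, and 25 adjusted over the list alone (median 2.17, camera adjusted p = 8.47e-16; adjusted p = 0.37 with an estimated correlation). Inflammatory genes had a median of −0.88, with 3 of 20 lower, and 7 adjusted over the list alone (camera adjusted p = 7.91e-05; adjusted p = 0.16 with an estimated correlation, 0.031 by fry). In all 481 genes passed in limma, 257 higher and 224 lower after miR-21. The count was 86, 124 or 165 without miR-21 1, 2 or 3 and 402, 187 or 135 without miR-324 1, 2 or 4; Pmp2 and Col1a2 passed in each of these fits and Actg2 in none (adjusted p = 0.063 to 0.12). Postn failed without miR-21 1, Prl and Dll4 passed only without miR-324 1, Ifit3b only without miR-324 1 or 2, and Cmpk2 only without a miR-324 array. Scramble 3, which by its label had no miR-324, lay on the side of the miR-324 arrays in each of these genes. Prl stood at 14.92 there, Dll4 at 14.24, Ifit3b at 12.02 and Cmpk2 at 9.91. Pmp2 stood at 4.24, Col1a2 at 8.40, Actg2 at 3.78 and Postn at 9.35. A difference between cultures can therefore not be told apart from the miRNAs in these genes.

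Between miR-34a and miR-324 no gene passed in limma (0 of 19572, with 2544 or 13.0% at an unadjusted p under 0.05, and 869 of them at least 2-fold different). The genes with the smallest p had adjusted p = 0.32 and were Tpmt (1.24 ± 0.23), Eif5a2 (1.46 ± 0.28), Ctps2 (1.14) and Efhc2 (1.12) on the higher side and Notch4 (−1.57 ± 0.28), Dgat1 (−1.53 ± 0.27), Slfn10-ps (−1.60 ± 0.26) and Arhgap23 (−1.45 ± 0.25) on the lower side. Macrophage markers had higher means after miR-34a, with a median of 2.40, 0 of 17 past over all genes and 1 adjusted over the list alone (camera adjusted p = 5.43e-09; adjusted p = 0.37 with an estimated correlation). Endothelial markers had −1.96, with 0 of 14 past and 5 lower adjusted over the list alone (2.86e-07; adjusted p = 0.37 with an estimated correlation), and interferon genes −1.21, with 0 of 26 past and 13 lower adjusted over the list alone (2.37e-08; adjusted p = 0.38 with an estimated correlation). In miR-34a 3 the macrophage signal (4.72) was close to that of the miR-324 arrays (4.49 to 4.70) and the endothelial signal (11.93) within theirs (11.77 to 13.13), against 9.20 and 8.79, and 9.64 and 9.47, in miR-34a 1 and 2. Without miR-34a 3 the count was 801, without miR-324 2 it was 1, and without any 1 of the others 0. Over the 25 lists camera called 11 between miR-34a and miR-21, 12 between miR-34a and miR-324 and 14 between miR-21 and miR-324. With an estimated correlation 0 of these calls held, and fry called 0, 0 and 2.

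The differences from scramble correlated across genes at 0.592 for miR-21 and miR-34a, 0.441 for miR-21 and miR-324 and 0.414 for miR-34a and miR-324. Simulated unchanged groups, compared with 1 simulated scramble group, gave 0.501, 0.502 and 0.498, since the comparisons share their controls. The simulation used each gene's spread from the fit of all groups, not the values of the scramble arrays, among which scramble 3 stood apart. The covariances were 0.129, 0.182 and 0.087 against 0.069 in the simulation, differences of 0.060, 0.112 and 0.018. The simulation draws each group independently and so leaves out the label suffixes that groups share; with the suffix as a fixed block the correlations were 0.231, 0.377 and 0.212. No gene was called in 2 comparisons with scramble, and independent lists would share 0, because 2 of the comparisons had no calls. The 3 scramble arrays cannot be split into parts of 2 each, so part of any excess may come from the shared controls.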

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

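The tests of explanations and the counts over other splits in this part were chosen only after the results they bear on were seen, except the count of pituitary receptor and regulator genes; the fits with the label suffix, within suffix A or without 1 array were fixed earlier.

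Among the 2634 probes with no gene name here, which enter no comparison of the report, 6 passed the limma threshold in miR-21 against scramble, 4 higher and 2 lower. None did in miR-34a or miR-324 against scramble. Between miRNAs 6 passed in miR-34a against miR-21, 0 in miR-34a against miR-324 and 27 in miR-21 against miR-324. The check for a single outlying sample was not applied, since it needs groups larger than 3.

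Interferon response genes had list medians of 5.31 to 5.89 in the miR-21 arrays and of 6.88 or more in the other arrays, and endothelial markers, 8.23 to 8.88 in the miR-21 arrays and 9.36 or more in the others, were lowest in the same arrays. Cultures with Y-linked transcripts and fewer macrophages both stay open: miR-34a 3 and miR-324 1, the other arrays with the highest Eif2s3y, and the 5 other arrays with as few macrophage transcripts (list median at or below 5.44) had interferon medians at least 2.03 above the highest miR-21 array, but all of these arrays had endothelial medians of 11.53 or more, so none is matched to miR-21. Fewer endothelial cells stay open as well, since the interferon median less the endothelial one was −3.57 to −2.51 in the miR-21 arrays and −2.54 to −2.37 in scramble, with the lowest scramble array at −0.04 from the highest miR-21 array. Without scramble 3 the median difference of the endothelial markers was only −0.13, against −1.09 for the interferon list, although the endothelial list medians remained lowest in the miR-21 arrays. A batch of the miR-21 arrays alone cannot be told apart from miR-21, because 0 miR-21 arrays share a label suffix with a scramble array. An effect of miR-21 on the interferon response stays beside these as untested, and the list's median was −2.59 with the label suffix as a fixed block, a fit that reaches miR-21 through arrays of other miRNAs without a suffix, and −1.09 without scramble 3. The Eif2s3y covariate did not shrink the list's median difference. That fit rests mainly on differences within miR-34a and miR-324, whose arrays with the highest Eif2s3y are the unmatched ones, so it does not decide.

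The miR-324 arrays had more endothelial and fewer macrophage transcripts than scramble, by 2.37 and −2.59 in the list medians. If the labels are right, a fall of this size in macrophage markers also arose without miR-324. Scramble 3 and miR-34a 3, which had none, differed by −3.93 and −3.52 from the other arrays of their groups. So miR-324 is not needed for such a fall, but this does not tell what lowered these markers in the miR-324 arrays. A culture or preparation that scramble 3 shared with the miR-324 arrays is a candidate explanation of the endothelial part: within the pair that shares suffix B the endothelial shift was 0.42 (95% interval 0.08 to 0.81 over 10000 resamples of the list's genes), with all 14 markers still higher in miR-324 2. Endothelial markers were 1.91 higher in scramble 3 and 2.97 higher in miR-34a 3 than in the other arrays of their groups. Yet miR-34a 3 carries no suffix and had Prl at only 4.01, so high endothelial markers also arose without miR-324 and without that culture's marks. The macrophage shift of −0.49 (−1.01 to 0.23) decides nothing, since that list lay only 1.08 above the floor probes in scramble 3 and no fall of the size between the groups could have been seen. An effect of miR-324 on the endothelial part stays open, as the pair is 1 array against 1. For the macrophage part miR-324 and a shared culture both stay open.

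The pituitary hormone transcripts Prl (14.26 to 15.17) and Cga (8.69 to 12.82) stood far above the floor in scramble 3 and the miR-324 arrays, while Gh stood at 10.17 in scramble 3 and 4.45, 9.15 and 8.34 in miR-324 1, 2 and 4, and Tshb at 4.69 to 4.99 in these arrays. Pomc stood at 5.99 to 7.41 in these arrays against 4.79 to 5.61 in the other 8, and Lhb at 4.03 to 6.23 against 3.21 to 3.56. Fshb overlapped, at 4.84 to 6.16 against 3.86 to 5.67. A change made by miR-324 is excluded as the whole cause unless scramble 3 is mislabelled, because Prl in scramble 3 lay 10.09 above the higher of scramble 1 and 2. Pituitary tissue, which lies close to the trigeminal ganglia, is a candidate source if it was carried into these cultures. Of 10 pituitary receptor and regulator genes not looked at before, 1 (Tgfbr3l) was higher in each of these 4 arrays than in the other 8, but only 2 of the 10 stood above 6 in any array, so the test leaves this open. Whether scramble 3 is mislabelled was not tested.

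With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For miR-21 against scramble 1 of the 10 splits, the real one, gave as many calls (204, highest other 0), and likewise 1 for miR-34a against miR-21 (31, highest other 0) and 1 for miR-21 against miR-324 (481, highest other 0). For miR-34a against scramble the real count was 0 and the highest other 0, so 10 of 10 gave as many. For miR-324 against scramble it was 0 and the highest other 93 (10 of 10), from scramble 1 and 2 with miR-324 1 set against scramble 3 with miR-324 2 and 4. For miR-34a against miR-324 it was 0 and the highest other 253 (10 of 10), from miR-34a 1 and 2 with miR-324 2 set against miR-34a 3 with miR-324 1 and 4. These last splits point to a structure of the samples other than the groups. The first of them keeps the arrays of suffix A and those of suffix B on opposite sides, and with the suffix as a fixed block miR-324 against scramble gave 0 calls. The second sets arrays with a suffix, where Eif2s3y was 2.27 to 2.96, against arrays without one, where it was 5.13 to 8.53. Within suffix A, miR-34a 1 and 2 against scramble 1 and 2 gave 0 calls in limma (762 genes, or 3.89%, at an unadjusted p under 0.05).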

How the results depend on the processing

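The settings with the level of Eif2s3y as a covariate and with scramble 3, miR-34a 3 and miR-324 1 left out together were tests chosen only after the results were seen; the others were fixed earlier. Counts are of genes past the limma threshold, where the reported counts were 204 for miR-21, 0 for miR-34a and 0 for miR-324 against scramble, 31 for miR-34a against miR-21, 0 for miR-34a against miR-324 and 481 for miR-21 against miR-324. Quantile normalization again gave 260, 39 and 507 for the comparisons with calls, median centring 214, 27 and 454, and a variance trend 196, 30 and 455, all within 1.5 times, and the comparisons without calls stayed at 0 there. Only bright probes gave 47 for miR-34a against miR-21. Array weights gave 2390 for miR-21 and 2589 for miR-324 against scramble, and 2148, 2806 and 1788 between miRNAs (miR-34a against miR-21, miR-34a against miR-324, miR-21 against miR-324); the weights were lowest for miR-34a 3 (0.251) and scramble 3 (0.403). Only the groups compared in the fit gave 906 for miR-21, 1 for miR-34a against miR-324 and 1043 for miR-21 against miR-324. Without moderation the counts were 17 for miR-21, 14 for miR-34a against miR-21 and 53 for miR-21 against miR-324. An unadjusted p under 0.05 with at least a 2-fold difference gave 1419, 32 and 1146 for miR-21, miR-34a and miR-324 against scramble and 728, 869 and 1400 between miRNAs in the order above.

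The label number as a replicate block gave 2 for miR-21, 5 for miR-34a against miR-21 and 23 for miR-21 against miR-324, with 5 residual degrees of freedom. A pairing of the samples by number was not seen. Deviations of arrays with the same number correlated above 0.1 in 3 of 16 pairs (−0.412 to 0.360), against 4 of 5 pairs with the same suffix (0.009 to 0.360). The highest values came from pairs that share neither, scramble 3 with miR-34a 3 (0.475) and miR-34a 3 with miR-324 1 (0.477). These correlations thus do not show that the suffix pairs the samples, and they cannot exclude a pairing by number. The label suffix as a fixed block gave 684 for miR-21, 1004 for miR-34a against miR-21 and 1354 for miR-21 against miR-324, and as a random block (correlation 0.282) 34 for miR-21 and 803 for miR-21 against miR-324. The Eif2s3y covariate gave 89, 169 and 1192 for the comparisons with calls. It cannot tell cultures with Y-linked transcripts from miR-21, since Eif2s3y was high in every miR-21 array and in no scramble array. Without the 3 arrays that stand apart the counts were 2553 for miR-21 and 2587 for miR-324 against scramble, and 2338, 2215 and 2380 between miRNAs. These arrays were chosen because they differ from their groups, so leaving them out lowers the spread within groups by construction. Without scramble 3 the scramble arrays had Prl at 3.42 and 4.83, against 14.26 and 15.17 in miR-324 2 and 4. A difference between cultures can then not be told apart from miR-324. Leaving out 1 array gave 11 to 81 for miR-21, 0 in each fit for miR-34a, 0 to 383 for miR-324 (383 without scramble 3), 2 to 537 for miR-34a against miR-21 and 0 to 801 for miR-34a against miR-324 (537 and 801 without miR-34a 3), and 86 to 402 for miR-21 against miR-324. Oasl2 and Irf9 passed in miR-21 with the suffix as a fixed block (adjusted p = 0.0041 and 0.0016), as a random block (0.015 and 0.015) and with the Eif2s3y covariate (0.022 and 0.016), and not under the replicate block (0.070 and 0.070).

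Of the 32 list calls against scramble 0 held with an estimated correlation and 0 with fry; neither method moves the medians. The direction of lists called in the reported or the other fit turned with the suffix as a fixed block in miR-21 (sensory neuron 1.53, pan-neuronal 0.98, axon 0.51, macrophage 0.69, p53 targets −0.49), miR-34a (cholesterol 0.04) and miR-324 (sensory neuron 0.17, pan-neuronal 0.31, axon 0.23, nerve injury 0.20, fibroblast 0.15, cell cycle 0.40, p53 targets −0.08). With the Eif2s3y covariate they did so in miR-21 (sensory neuron 1.23, pan-neuronal 1.16, axon 0.56, macrophage 0.15, p53 targets −0.45) and miR-34a (sensory neuron 0.32, pan-neuronal 0.13, axon 0.24, endothelial −0.51, macrophage 0.63, cell cycle 0.45, p53 targets −0.16, cholesterol 0.27), and nerve injury genes in miR-324 were at 0.00. Without the 3 arrays that stand apart they did so in miR-34a for sensory neuron (0.05), pan-neuronal (0.03), nerve injury (0.07) and interferon genes (0.09), and cholesterol genes were at 0.00. Leaving out 1 array gave ranges across 0 in miR-34a for sensory neuron (−1.25 to 0.38), pan-neuronal (−1.50 to 0.18), axon (−0.34 to 0.19), fibroblast (−0.43 to 0.32), endothelial (−0.63 to 1.07), macrophage (−1.21 to 1.06), cell cycle (−0.76 to 0.82), p53 target (−0.21 to 0.38), cholesterol (−0.49 to 0.33) and reported miR-34a target genes (−0.07 to 0.19), which crossed 0 without miR-34a 3, as did nerve injury genes (−0.45 to 0.06), and for interferon genes (−0.65 to 0.22), which did so without scramble 3. Some lists without calls crossed 0 too, such as satellite glia markers (−0.18 to 0.57 in miR-34a and −0.08 to 0.89 in miR-21). The interferon list in miR-21 stayed below 0 under each setting in which its median was computed again: −2.59 with the suffix as a fixed block, −2.34 with the Eif2s3y covariate, −1.09 without the 3 arrays, and −2.43 to −1.09 without 1 array. Leaving out the 3 arrays removes only scramble 3 from this comparison, so its median is by construction the one without scramble 3. Lists between miRNAs were not refitted.

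The correlation of miR-21 and miR-34a differences was 0.231 with the suffix as a fixed block and 0.612 to 0.668 without 1 scramble array; that of miR-21 and miR-324 was 0.377 and 0.400 to 0.615 likewise, and that of miR-34a and miR-324 0.212 and 0.289 to 0.759. For each of these changes the cause was not tested, apart from settings that by construction test fewer probes or use fewer arrays. Seed sites, and their alternatives, were not run because no 3′ untranslated regions were used here. The pair of arrays of suffix B gives differences with no test. Genes near the floor, where olfactory and vomeronasal receptor probes had medians of 3.51 to 4.12, have compressed differences.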

Other observations

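The gene lists of this part were tests chosen only after the results were seen, and all of them come from the limma fit of the report.

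Of 41 extracellular matrix genes 14 rose, 0 fell and 27 did not pass after miR-21 (median 1.62), while none passed after miR-34a (0.31) or miR-324 (0.18). After miR-21 the mean was higher for 35 and lower for 6, among them Dcn (−2.65, adjusted p = 0.17) and Lum (−1.59, adjusted p = 0.52), singled out after their values were seen. Those past the threshold include genes the report does not give for miR-21 against scramble. The laminin chains Lama2, Lamb1 and Lamc1, parts of the sheet that Schwann cells lay down around axons, rose by 2.81 ± 0.41, 1.27 ± 0.24 and 1.86 ± 0.29 (adjusted p = 0.014, 0.029 and 0.017), and the heparan sulfate proteoglycan Agrn by 2.38 ± 0.48 (adjusted p = 0.040). The small leucine-rich proteoglycans Fmod, Prelp and Ogn rose by 2.90, 2.95 and 2.01 (adjusted p = 0.017, 0.019 and 0.031), and Ltbp2 and Efemp1, which bind elastic fibres, by 3.21 and 2.27 (adjusted p = 0.015 and 0.013). Some of these genes were also high in miR-34a 3 and miR-324 1, the other arrays with the highest Eif2s3y: Agrn stood at 9.10 and 9.25 there, against 9.33 to 9.72 after miR-21 and 6.81 to 7.24 in scramble. Lama2 did not, at 8.45 and 7.08 against 7.61 to 9.19 in scramble. Because the list was drawn up after Col1a2, Hspg2, Lox and Tnn had been seen to rise, its count is not independent evidence, and the list was neither tested as a set nor refitted without single arrays.

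Among genes of the circadian clock, Arntl, the core activator Bmal1, rose after miR-21 by 1.59 ± 0.25 (11.28 ± 0.18 against 9.70 ± 0.46, SD, n = 3; adjusted p = 0.017) and was lower after miR-34a than after miR-21 (−1.55, adjusted p = 0.036). Its repressors did not pass, with Per1 at −0.84 ± 0.27 and Nr1d1 at −0.41 ± 0.29 (adjusted p = 0.15 and 0.50), and its partner Clock differed by 0.10 ± 0.24 (adjusted p = 0.86). Of 18 clock genes 1 rose and 17 did not pass after miR-21 (median −0.17), and none passed after miR-34a (0.08) or miR-324 (0.15).

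Y-linked genes (3 measured) had median differences from scramble of 4.11 for miR-21, 1.87 for miR-34a and 2.53 for miR-324, and pituitary hormone genes (7 measured) of −0.55, −1 and 1.12, with none past the threshold in these comparisons. Single arrays carry some of these values. The Y-linked median was 8.53 in miR-34a 3 and 3.74 and 3.18 in miR-34a 1 and 2, and 7.88, 2.96 and 5.13 in miR-324 1, 2 and 4, and the pituitary median was 7.38 in scramble 3 and 3.67 and 3.95 in scramble 1 and 2.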
